A study of Homo sapiens with 24 samples.

How the data were processed

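Thawed PBMCs of 2 donors were plated, given JRD-SIK1/2i-3 at 1 or 10 µM or its solvent for 1 h, then LPS at 5 ng/mL for 1, 4 or 24 h, and loaded as adherent and non-adherent cells together on the Chromium 3' version 3 assay, per the labels' protocols. The groups without LPS received no compound. The authors deposited 1 matrix of whole-number UMI counts for all libraries, made with Cell Ranger 3.0.2 per the file header and on GRCh38 per the submitters' processing notes. The annotation, the cell-calling settings and any equalisation of depth between libraries are not given in the sources used here. The matrix held 33538 genes and 111266 barcodes with at least 500 UMIs each, and the barcode suffix assigned each to 1 of the 24 libraries. Cell types were named here from marker genes and can differ from the authors' own. Y-linked genes and X inactivation transcripts (102 in all) were left out of every step, leaving 33436 genes, of which 33354 were found by identifier in GENCODE 29 for positions on GRCh38.

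Barcodes with fewer than 300 genes (2680) or more than 20% mitochondrial UMIs (7382) were left out, 7550 in all, leaving 103716. Doublets were scored per library with Scrublet (scanpy 1.11.5, expected rate 0.05); 1 score threshold of 0.244, the median of the libraries' automatic thresholds (0.202 to 0.449), marked 2116 cells (2.04%), which were removed. Cells were clustered with leidenalg 0.10.2 (resolution 1, seed 1) on a shared nearest neighbour graph of 20 neighbours over 30 principal components of 2000 variable genes, giving 43 clusters (27 at resolution 0.5). A cluster was called monocyte-like, T-like, NK-like or B-like from markers fixed before the data were examined, and stayed unnamed where other markers led it, fewer than 3 markers were detected, its median UMI count was under 1/3 of its libraries' with no marker among its top 10 genes, or over 50% of its cells were doublets. A further rule, added after the clusters were seen, left clusters 16, 18 and 26 (CD3 genes in clusters with NK genes) and 36 (dendritic genes) unnamed. The unnamed share differed by −0.289 points between LPS and no LPS, and by 0.357 and 0.743 points between 10 or 1 µM and 0 µM. In total 174 platelet-like and 122 progenitor-like cells were not tested.

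UMI counts were summed per library and class, since cells are not replicates. Monocyte-like sums held 1796813 to 8748357 UMIs from 127 to 883 cells per library, T-like sums 7303076 to 14462761, NK-like sums 470592 to 3016785 and B-like sums 1763294 to 3822514. Each class was fitted with edgeR 4.0.16 (R 4.3.3; filterByExpr, TMM, quasi-likelihood test) over all 24 libraries with 12 groups and no donor term, so that all groups shared 1 estimate of the spread. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Tested were 12073 genes in monocyte-like, 13718 in T-like, 10436 in NK-like and 11121 in B-like cells. Values are log2 fold changes ± SE with n = 2 libraries per group; CPM are means of the 2 libraries. Where a group had 0 counts of a gene, the fold is a lower bound against 3 counts over the group; with 1 to 3 counts the ratio of counts is given with an exact 95% interval. Such bounds and intervals cover counting error only, and UMI counts remove PCR copies. On simulated counts built on the comparison of 10 µM with 0 µM at 24 h, 100 genes were changed 2-fold and 100 changed 4-fold. The changed genes were drawn from those above 10 CPM, and no donor differences were simulated. The test recovered 54% and 92% in monocyte-like cells (10487 genes) and 70% and 97% in T-like (13016). It recovered 57% and 95% in NK-like (9939) and 59% and 99% in B-like cells (10479). False calls numbered 4, 8, 5 and 11. These rates do not cover genes at lower counts.

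Replicate numbers pair the libraries because the labels give the same donor for each number. As a check, deviations from the group means over 3000 genes correlated within donor over 66 pairs of groups with a median r of 0.256 (0.0685 to 0.673) in monocyte-like, 0.783 (0.666 to 0.936) in T-like, 0.404 (0.288 to 0.617) in NK-like and 0.349 (0.0905 to 0.645) in B-like cells. The same fit with a donor block was an alternative; its value stands beside a result where it changes the call or moves a count by more than 1.5 times.

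The genes named were set by a rule fixed, like the comparisons, tests and lists, before the data were examined. In monocyte-like cells it takes up to 6 largest rises and 6 largest falls among genes that passed, with at least 50 CPM in the higher group and the same direction in both donors, 15 key genes whatever their p, and up to 4 members of each list with the smallest p; in the other classes it takes up to 5 each way. Genes whose level can follow a donor's own genome were not named. The 21 lists, of which 1 is not reported, were pro-inflammatory cytokines, chemokines, anti-inflammatory regulators, CREB/CRTC targets, SIK pathway components, interferon-stimulated genes, NF-kB targets, prostaglandin and inflammasome genes, MHC class II and costimulation, monocyte identity and scavenger receptors, metallothioneins, glycolysis and hypoxia, cholesterol synthesis, heat shock and unfolded protein stress, lymphocyte activation, and markers of T and NK cells, B cells, platelets, dendritic cells and neutrophils. For each, members that passed over all genes are counted, with the count adjusted over the list alone where it differs. The p beside the count is from limma 3.58.1's camera (preset correlation 0.01, adjusted over all lists and comparisons of the class). Estimated correlations were often above 0.01, and the adjusted p was then often far larger, also where the call held.

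Alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0, the donor block, a fit of 1 time point, stricter cell filters (at least 800 genes and at most 10% mitochondrial UMIs, 47994 cells), doublets kept, sums thinned to the smallest total, resolution 0.5 for shares, genes far higher in monocyte-like cells left out of the lymphoid tests, and leaving out each library, where the lone library of a group is assumed to vary like the others. Leaving out the CD16 monocyte cluster was added after the data were seen. Shares were compared by exact sign-flip permutation tests over 6 pairs. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, python-igraph 0.11.9 and matplotlib 3.10.9 were used.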

Results

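The data are single-cell RNA profiles of peripheral blood mononuclear cells (PBMCs: monocytes, T, NK and B cells of blood) from 2 donors. Cells were treated for 1 h with JRD-SIK1/2i-3, a code-named compound whose name states an inhibitor of the salt-inducible kinases SIK1 and SIK2, or with solvent. They were then given 5 ng/mL lipopolysaccharide (LPS, a bacterial cell wall component sensed through TLR4) for 1, 4 or 24 h. The 12 groups of 2 libraries were no LPS, LPS alone, LPS with 1 µM and LPS with 10 µM of the compound, each at the 3 times. No group held the compound without LPS. Replicates 1 and 2 of every group are the 2 donors. The 24 libraries held 111266 barcodes and 537004257 UMIs (unique molecular identifiers, 1 per captured transcript). A library had 15731486 to 27300534 UMIs and 3106 to 6484 barcodes. After filtering, 101600 cells were kept, 3012 to 5744 per library, with a median of 3602.5 to 4866 UMIs per cell.

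Of the cells kept, 57974 were T-like, 14806 B-like, 12061 NK-like and 9442 monocyte-like by their marker genes. A further 7021 stayed unnamed (2.618 to 9.445% of a library). Monocyte-like cells made up less of the LPS libraries than of the libraries without LPS, 5.6% against 14.8% on average. The difference was −9.21 percentage points ± 2.44 (SD of 6 pairs of the same donor and time), lower in 6 of 6 pairs. With 10 µM under LPS their share was 8.89% (3.29 points ± 2.28 above LPS alone, higher in 6 of 6 pairs), and with 1 µM 7.31% (1.71 points ± 1.28, higher in 6 of 6 pairs). The T-like share was 59% with LPS against 52.2% without (6.73 points ± 1.99, higher in 6 of 6 pairs). With 10 µM the T-like and B-like shares differed from LPS alone by −2.05 and −1.91 points, each higher in 1 of 6 pairs. The NK-like share differed by 0.339 points, higher in 3 of 6 (−2.54 points with stricter cell filters). Shares of a library add up to the whole, so a lower monocyte-like share by itself raises the others. These tests therefore cannot separate the T-like, B-like and NK-like differences from the monocyte-like ones. A change of the monocyte-like share alone would move the others in proportion to their size. With 10 µM the B-like share, 15.9% with LPS alone, lost nearly as many points as the T-like share, 59%. Shares among the other cells were not tested, so a B-like change of its own stays open. By an exact two-sided sign-flip permutation test the 3 monocyte-like differences had p = 0.03125, the smallest that 6 pairs allow, and adjusted p = 0.0625 over the 12 share tests. None of the 12 passed, and with 6 pairs a test passes only when many others also sit at the smallest p. The 6 pairs come from 2 donors and are not independent people.

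**Figure D1:**
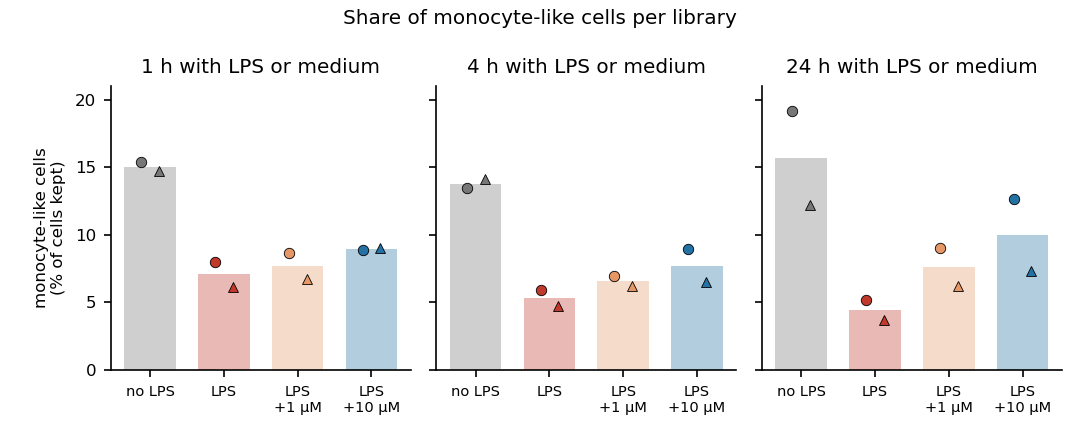
Share of the cells kept that were monocyte-like (%), by group, at 1, 4 and 24 h after LPS. Bars are means of the 2 libraries, circles donor 1 and triangles donor 2. At each time both libraries with LPS alone lie below both libraries without LPS, and the mean with 10 µM lies above that with LPS alone.

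The comparison of LPS with no LPS asked how the cells answered the stimulus alone. At 1 h, inflammatory transcripts rose in monocyte-like cells. IFNB1, which encodes interferon beta, was at least 302-fold (at least 82.1-fold whichever library was left out) higher, and the cytokine genes IL6 and TNF rose by 8.62 ± 0.80 and 7.17 ± 0.45 on the log2 scale (SE; TNF 4786 against 33.2 CPM). CCL4, a chemokine gene, rose by 7.68 ± 0.62 and ACOD1, which encodes the enzyme that makes itaconate, by 7.52 ± 0.66. In all, 403 genes rose and 121 fell of 12073 tested. Of the pro-inflammatory cytokines 8 of 19 rose (11 rose adjusted over the list alone), adjusted p = 1.6e-23. Of the chemokines 9 of 22 rose (10 rose adjusted over the list alone), adjusted p = 5.2e-19. Of the NF-kB targets 21 of 26 rose (24 rose adjusted over the list alone), adjusted p = 3.7e-87. Among the last were the inhibitors NFKBIA (3.32 ± 0.23) and TNFAIP3 (4.03 ± 0.25) and the adhesion gene ICAM1 (3.50 ± 0.16). Anti-inflammatory regulators rose too (11 of 25 rose (12 rose adjusted over the list alone), adjusted p = 2.7e-20), with IL1RN, the interleukin 1 receptor antagonist, at 3.32 ± 0.36 and SOCS3 at 3.00 ± 0.30. Of the CREB/CRTC targets, genes driven by the cAMP-responsive factor CREB, 10 of 27 rose (11 rose adjusted over the list alone), adjusted p = 1.6e-08, adjusted p = 0.12 with an estimated correlation. EGR1 rose by 4.75 ± 0.56 and NR4A1 by 2.19 ± 0.30. Of the interferon-stimulated genes 9 of 40 rose (10 rose adjusted over the list alone), adjusted p = 3.8e-05, adjusted p = 0.64 with an estimated correlation, IFIT3 by 6.07 ± 0.73. Of the lymphocyte activation list, which shares TNF, CCL3, CCL4 and NR4A1 with other lists, 10 of 28 rose (13 rose and 1 fell adjusted over the list alone), adjusted p = 1.1e-23. Of prostaglandin and inflammasome genes 4 of 16 rose, adjusted p = 8e-08, with PTGS2, the inducible cyclooxygenase, at 3.31 ± 0.28 and NLRP3 at 3.96 ± 0.28. The largest falls were in IFI30 (−2.05 ± 0.32) and TXNIP (−1.39 ± 0.26). IL10, CCL2 and NR4A2 did not pass (adjusted p = 0.41, 0.94 and 0.61). Nor did CXCL10 (3.76, adjusted p = 0.24; 0.021 with a donor block). Of genes of other cells, T and NK markers gave 1 of 12 rose, adjusted p = 0.013, adjusted p = 0.56 with an estimated correlation. Dendritic markers gave 1 of 9 rose (2 rose adjusted over the list alone), adjusted p = 0.033, adjusted p = 0.32 with an estimated correlation and adjusted p = 0.068 with a donor block. Monocyte-like cells without LPS came from clusters 24 (VCAN, LYZ and S100A8 high; 42.2%), 20 (the FCGR3A or CD16 type; 28.9%) and 30 (heat-shock gene HSPA1A high; 28.4%). Those with LPS came from clusters 27 (EREG and NLRP3 high; 43.7%), 20 (41.5%) and 30 (13.9%). The 524 genes became 322 without no LPS replicate 2, 298 without no LPS replicate 1 and 270 without LPS replicate 2. Of 53 named genes that passed, 40 did so whichever library was left out. There were 42, 46, 49 and 45 without no LPS replicate 2, no LPS replicate 1, LPS replicate 1 and LPS replicate 2.

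At 4 h the monocyte-like response was wider: 2059 genes rose and 2299 fell, 47.2% rising (53.4% with RLE size factors). IL6 rose by 13.91 ± 0.93 (10410 against 0.619 CPM), INHBA, which encodes activin A, by 9.80 ± 0.55, CCL3 by 8.81 ± 0.46 and IL23A, a subunit of interleukin 23, by 6.41 ± 0.96. IFNB1 was at least 127-fold (at least 59.4-fold whichever library was left out) and IL12B, a subunit of interleukins 12 and 23, at least 83.5-fold (at least 39-fold whichever library was left out) higher. Of the interferon-stimulated genes 37 of 40 rose, median 3.71, adjusted p = 5.7e-34. USP18 rose by 6.49 ± 0.34 and IFI44 by 5.67 ± 0.34. Of the cytokines 17 of 19 rose (18 rose adjusted over the list alone), adjusted p = 6.8e-18. The chemokine list gave 17 of 22 rose and 1 fell, adjusted p = 2.1e-11, and the NF-kB list 25 of 26 rose, adjusted p = 3.2e-42. TNF (6.75 ± 0.44), IL1B (6.72 ± 0.54), PTGS2 (6.41 ± 0.32), IL10 (3.55 ± 0.48) and CCL2 (3.24 ± 0.85) all rose. Of the MHC class II and costimulation genes 11 of 18 rose, adjusted p = 0.00073, adjusted p = 0.48 with an estimated correlation, CD80 by 6.60 ± 0.55. Of the heat shock and unfolded protein genes 13 of 24 rose and 4 fell (14 rose and 5 fell adjusted over the list alone), adjusted p = 0.00016, adjusted p = 0.16 with an estimated correlation, XBP1 by 3.17 ± 0.15. Monocyte identity genes fell (14 of 30 fell (15 fell adjusted over the list alone), adjusted p = 1.8e-05, adjusted p = 0.32 with an estimated correlation): VCAN by −4.39 ± 0.45, CSF1R, the receptor for macrophage colony-stimulating factor, by −3.88 ± 0.33 and CD14, the LPS co-receptor, by −2.85 ± 0.33. Of the SIK pathway components 1 of 18 rose and 8 fell (1 rose and 11 fell adjusted over the list alone), adjusted p = 0.087, HDAC9 rising by 4.34 ± 0.30 and HDAC5 and PRKACA changing by −2.43 ± 0.25 and −1.97 ± 0.26. Of the glycolysis and hypoxia genes 6 of 24 rose and 7 fell, median −0.20, adjusted p = 0.94 and mean 0.22. Of the cholesterol synthesis genes 5 of 20 rose and 1 fell, adjusted p = 0.18. The anti-inflammatory list gave 14 of 25 rose and 4 fell (16 rose and 4 fell adjusted over the list alone), adjusted p = 6.4e-10, and the CREB/CRTC list 13 of 27 rose and 3 fell (15 rose and 4 fell adjusted over the list alone), adjusted p = 0.0077, adjusted p = 0.56 with an estimated correlation. The prostaglandin and inflammasome list gave 9 of 16 rose and 3 fell, adjusted p = 0.0016, adjusted p = 0.12 with an estimated correlation, and lymphocyte activation 21 of 28 rose and 1 fell (23 rose and 1 fell adjusted over the list alone), adjusted p = 4.6e-20. Of the neutrophil markers 1 of 4 fell, adjusted p = 0.41. CXCL10 gave 2.79 (edgeR adjusted p = 0.14, and 0.012 with a donor block). Its level without LPS differed between donors 1 and 2, 528.5 and 19.1 CPM, against 2555 and 1223 CPM with LPS. Cells without LPS lay in clusters 24 (66.7%), 20 (28.1%) and 30 (5.02%). Cells with LPS lay in cluster 22 (98.9%; CCL4L2, whose reads may be shared with near-identical copies, and IL6 high). Of 83 named genes that passed, 76 did so whichever library was left out. There were 80 without no LPS replicate 1, LPS replicate 1 or LPS replicate 2, and 79 without no LPS replicate 2.

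At 24 h, 2445 genes rose and 2269 fell in monocyte-like cells. Some genes were absent without LPS: IL24 and SERPINB7 were at least 2200-fold (at least 957-fold whichever library was left out) and at least 1380-fold (at least 602-fold whichever library was left out) higher. IL6 (1 count without LPS) was 10600-fold (95% counting interval 1910 to 420000) higher, and at least 1370-fold whichever library was left out. CXCL5, a neutrophil chemokine gene, rose by 13.10 ± 1.11, IL1B by 10.24 ± 0.63 and CXCL8 by 9.67 ± 0.65. TNF was lower than at the earlier times but above cells without LPS (1.57 ± 0.36, 55.4 against 18.8 CPM). The difference between times was not tested. Genes of metallothioneins, zinc-binding proteins whose gene copies are alike in sequence so that single members are uncertain, rose as a list (10 of 10 rose, median 7.72, adjusted p = 1.8e-30). Of the chemokines 19 of 22 rose, adjusted p = 3e-15. Of the cytokines 15 of 19 rose and 1 fell, adjusted p = 3.4e-10. The NF-kB list gave 26 of 26 rose, adjusted p = 2e-36, and anti-inflammatory regulators 18 of 25 rose and 5 fell, adjusted p = 3.6e-13. Of the CREB/CRTC targets 18 of 27 rose and 3 fell (20 rose and 4 fell adjusted over the list alone), adjusted p = 2.5e-06, adjusted p = 0.19 with an estimated correlation, NR4A2 by 2.58 ± 0.79. Of the interferon-stimulated genes 34 of 40 rose (35 rose adjusted over the list alone), median 2.18, adjusted p = 1.5e-11, adjusted p = 0.22 with an estimated correlation, RSAD2 by 5.54 ± 0.58. Of the glycolysis and hypoxia genes 13 of 24 rose and 4 fell, adjusted p = 0.004, adjusted p = 0.27 with an estimated correlation. Of the lymphocyte activation list 22 of 28 rose (23 rose and 1 fell adjusted over the list alone), adjusted p = 3e-15. Of the identity and scavenger genes 6 of 30 rose and 15 fell, adjusted p = 0.0014, adjusted p = 0.47 with an estimated correlation, CD36 by −5.80 ± 0.41 and STAB1 by −6.32 ± 0.41. Of the MHC class II list 3 of 18 rose and 12 fell (3 rose and 13 fell adjusted over the list alone), adjusted p = 0.075, HLA-DMB by −3.69 ± 0.29. RNASE1 was at least 975-fold (at least 319-fold whichever library was left out) lower and GPNMB changed by −10.24 ± 0.59. Cells without LPS lay in cluster 28 (99.8%; FUCA1, GPNMB and RNASE1 high). Cells with LPS lay in cluster 23 (99.7%; CXCL5 and IL24 high). Transcripts typical of other cells rose in the same cells. Of the T and NK markers 7 of 12 rose, adjusted p = 0.016, adjusted p = 0.56 with an estimated correlation, NKG7 by 3.02 ± 0.43. Of the B markers 5 of 8 rose and 1 fell, adjusted p = 0.39, MS4A1 by 3.45 ± 0.87. Of the platelet markers 4 of 8 rose, adjusted p = 0.17, PPBP by 6.72 ± 1.12. Of 95 named genes that passed, 82 did so whichever library was left out. There were 90, 88, 93 and 90 without LPS replicate 1, LPS replicate 2, no LPS replicate 1 and no LPS replicate 2.

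**Figure D2:**
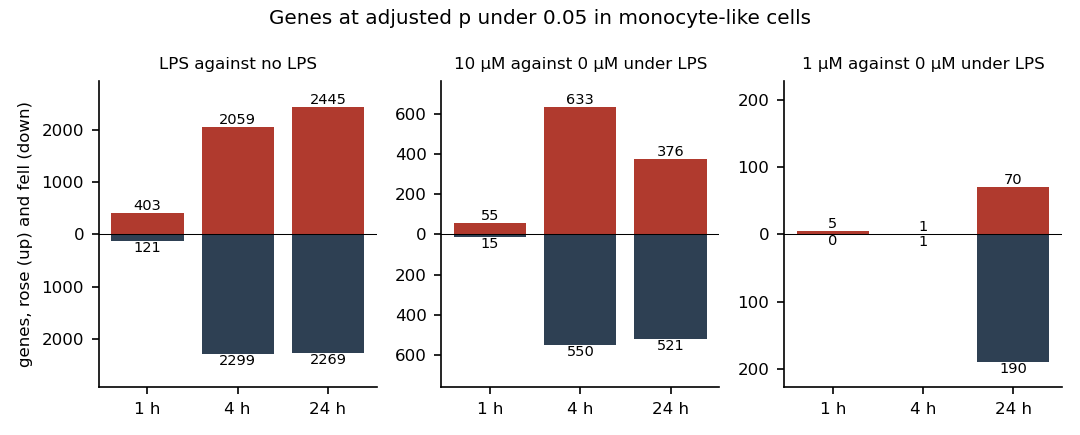
Number of genes that rose or fell in monocyte-like cells in each comparison, by time. Bars count genes that passed the edgeR test among 12073. LPS changed 524, 4358 and 4714 genes at 1, 4 and 24 h, and 10 µM under LPS 70, 1183 and 897.

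The comparison of 10 µM with 0 µM under LPS asked how the compound changed that response. At 1 h it raised CREB/CRTC targets in monocyte-like cells: of this list 8 of 27 rose (14 rose adjusted over the list alone), median 0.93, adjusted p = 1.4e-19. PDE4D, a cAMP phosphodiesterase gene, rose by 2.47 ± 0.30, the nuclear receptor genes NR4A2 and NR4A3 by 2.73 ± 0.39 (635 against 95.5 CPM) and 2.41 ± 0.37, THBS1 by 5.95 ± 0.92 and AREG by 3.16 ± 0.56. IL10, an anti-inflammatory cytokine gene, rose by 2.35 ± 0.49 (adjusted p = 0.034; 66.7 against 13 CPM) and PTGS2 by 1.74 ± 0.26. TNF fell, −1.72 ± 0.35 (adjusted p = 0.029; 1454 against 4786 CPM), and so did CCL7 (−4.00 ± 0.66) and MYC (−1.70 ± 0.30). IL6 (0.42 ± 0.52), IL1B (0.12 ± 0.42) and CXCL8 (0.60 ± 0.45) did not pass. CCL2 gave −2.91 ± 0.88 (adjusted p = 0.23). Of the cytokines 1 of 19 rose and 1 fell (2 rose and 3 fell adjusted over the list alone), adjusted p = 0.63. Of the chemokines 1 of 22 fell (3 fell adjusted over the list alone), adjusted p = 0.041, adjusted p = 0.19 with an estimated correlation, and adjusted p = 0.34 with a donor block. Of the interferon-stimulated genes 0 of 40 passed (2 fell adjusted over the list alone), median −0.38, adjusted p = 0.0022, adjusted p = 0.72 with an estimated correlation. Of the NF-kB targets 0 of 26 passed (2 rose adjusted over the list alone), median 0.13, adjusted p = 0.02, adjusted p = 0.60 with an estimated correlation. Of lymphocyte activation genes 2 of 28 fell (1 rose and 3 fell adjusted over the list alone), adjusted p = 0.0065, adjusted p = 0.22 with an estimated correlation. NR4A1 had adjusted p = 0.23 (0.042 with a donor block) and IFNB1, at −2.31 ± 0.85, adjusted p = 0.44 (0.0016 with the block). No list of other cell types passed. Cells with 10 µM lay in clusters 27 (54.8%), 20 (32.1%) and 30 (12.2%). In all 55 genes rose and 15 fell, 70 together, and a donor block gave 133 and 34. Leaving out LPS replicate 1, LPS replicate 2 or 10 µM replicate 2 gave 14, 13 or 19. Of 20 named genes that passed, 4 (DUSP4, PDE4D, SLC2A3 and LINC01588) did so whichever library was left out. There were 10, 6, 14 and 11 without LPS replicate 1, LPS replicate 2, 10 µM replicate 1 and 10 µM replicate 2. TNF had adjusted p = 0.33, 0.24 and 0.094 without LPS replicate 2, 10 µM replicate 1 and 10 µM replicate 2. IL10 had 0.31, 0.28, 0.066 and 0.26 without LPS replicate 1, LPS replicate 2, 10 µM replicate 1 and 10 µM replicate 2. NR4A2 had 0.055 and 0.051 and PTGS2 0.061 and 0.068 without LPS replicates 1 and 2.

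At 4 h, 633 genes rose and 550 fell with 10 µM. CREB/CRTC targets rose again (11 of 27 rose and 1 fell, median 0.59, adjusted p = 1.5e-06, adjusted p = 0.19 with an estimated correlation): PDE4D by 4.27 ± 0.38 (103 against 5.53 CPM), NR4A2 by 3.56 ± 0.45 (189 against 15.3 CPM), FOSB by 2.61 ± 0.41, CREM, a CREB family repressor and activator gene, by 2.56 ± 0.39 and VEGFA by 2.06 ± 0.41. TNF fell, −2.79 ± 0.36 (adjusted p = 0.00018; 671 against 4663 CPM), with CCL2 (−3.17 ± 0.85, adjusted p = 0.023; 526 against 4742 CPM), CCL7 (−3.79 ± 0.59), CCL5 (−2.34 ± 0.40) and TNFSF14 (−1.38 ± 0.27). IL6 (0.04 ± 0.51), IL1B (0.16 ± 0.42), CXCL8 (0.29 ± 0.45), IL23A (−0.02 ± 0.71) and IL10 (0.59 ± 0.43) did not pass. The chemokine list went both ways (4 of 22 rose and 3 fell (4 rose and 7 fell adjusted over the list alone), adjusted p = 0.50), with CXCL5 rising by 4.30 ± 0.74. CCL3 gave −0.92 ± 0.33 (adjusted p = 0.088; 0.014 with a donor block). Of the cytokines 2 of 19 rose and 2 fell (2 rose and 3 fell adjusted over the list alone), adjusted p = 0.20, OSM and INHBA rising by 1.94 ± 0.34 and 1.34 ± 0.35. Of the interferon-stimulated genes 4 of 40 fell (6 fell adjusted over the list alone), median −0.77, adjusted p = 2.4e-07, adjusted p = 0.49 with an estimated correlation: RSAD2 by −1.79 ± 0.48, LY6E by −1.15 ± 0.34. The interferon factor gene IRF8 fell (−1.82 ± 0.36). IFNB1 gave −3.78 ± 1.26 (adjusted p = 0.085; 3e-04 with the block). Of the identity list 4 of 30 rose (5 rose adjusted over the list alone), adjusted p = 0.13, VCAN by 2.54 ± 0.42, TLR4 by 1.80 ± 0.30 and CD14 by 1.29 ± 0.33, VCAN and CD14 having fallen with LPS alone. Of the SIK pathway components 4 of 18 rose and 1 fell, adjusted p = 0.068, SIK2 by 1.83 ± 0.31 and HDAC9 by −2.92 ± 0.30. Of the heat shock list 2 of 24 rose and 3 fell (2 rose and 5 fell adjusted over the list alone), adjusted p = 0.16, HSPD1 by −1.43 ± 0.25. Of the glycolysis and hypoxia list 3 of 24 rose and 2 fell, adjusted p = 0.89, HIF1A by 1.85 ± 0.32. Of the prostaglandin list 2 of 16 rose and 3 fell (3 rose and 3 fell adjusted over the list alone), median −0.02, adjusted p = 0.85 with mean 0.05 and the test pointing down, PTGS2 by 0.88 ± 0.26 and PTGER4, a prostaglandin E2 receptor gene, by −0.91 ± 0.25. Of NF-kB targets 1 of 26 rose (0 adjusted over the list alone), adjusted p = 0.034, adjusted p = 0.67 with an estimated correlation. Of lymphocyte activation genes 1 of 28 rose and 2 fell, adjusted p = 0.026, adjusted p = 0.33 with an estimated correlation. Of the dendritic markers 1 of 9 fell, adjusted p = 0.45 (FSCN1, −1.78 ± 0.38). Cells with 10 µM lay in cluster 22 (99.1%). The 1183 genes became 420, 750, 750 and 497 without LPS replicate 1, LPS replicate 2, 10 µM replicate 1 and 10 µM replicate 2. Of the 54 named genes that passed, 28, 39, 38 and 30 still did so (24 whichever was left out, TNF among them). CCL2 had adjusted p = 0.09, 0.057, 0.13 and 0.14 without the same libraries in that order, and PTGS2 0.13, 0.18, 0.12 and 0.13. NR4A1 (1.74 ± 0.33) had 0.057 and 0.062 without LPS replicate 1 and 10 µM replicate 1.

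At 24 h, 376 genes rose and 521 fell with 10 µM, 41.9% rising (33.9% with RLE size factors). Every tested interferon-stimulated gene fell (40 of 40 fell, median −3.91, adjusted p = 6e-104): IFI44L by −6.85 ± 0.58, OAS1 by −4.49 ± 0.35 and IFI6 by −4.80 ± 0.35, and IFIT1 (3 counts with 10 µM) was 206-fold (95% counting interval 70 to 1000) lower. CXCL10, an interferon-induced chemokine gene, had 0 counts with 10 µM, at least 333-fold (at least 108-fold whichever library was left out) lower than with LPS alone (adjusted p = 0.046). IL23A rose by 4.31 ± 0.88 (edgeR adjusted p = 0.0046, 222 against 12.8 CPM). It had 36.24 and 407.8 CPM with 10 µM in donors 1 and 2, and 2.707 and 22.98 with LPS alone. CSF3 (3.27 ± 0.44), OSM (2.48 ± 0.34), CCL20 (3.47 ± 0.80) and VEGFA (3.50 ± 0.47) rose too. TNF fell, −1.86 ± 0.38 (edgeR adjusted p = 0.005, 15 against 55.4 CPM). IL12B, which like IL23A encodes a subunit of interleukin 23, had 3 counts with 10 µM and 55 with LPS alone. It was 32-fold (95% counting interval 10.4 to 160) lower, and at least 13-fold whichever library was left out. Of the cytokines 4 of 19 rose and 3 fell (7 rose and 5 fell adjusted over the list alone), median −0.69, adjusted p = 0.99, the mean also below 0 and the test pointing up. Of the chemokines 4 of 22 rose and 7 fell (5 rose and 11 fell adjusted over the list alone), median −1.33, adjusted p = 0.0072, adjusted p = 0.10 with an estimated correlation and adjusted p = 0.23 with a donor block, CCL8 by −9.69 ± 1.69, CCL18 by −4.95 ± 0.88 and CCL22 by −1.73 ± 0.32. Of the MHC class II and costimulation list 6 of 18 fell (8 fell adjusted over the list alone), adjusted p = 2e-07, adjusted p = 0.19 with an estimated correlation, CD80 by −2.31 ± 0.40, CD83 by −1.88 ± 0.20 and CD40 by −1.86 ± 0.34. The metallothionein list fell (6 of 10 fell (7 fell adjusted over the list alone), median −1.12, adjusted p = 5.2e-09), as did the lymphocyte activation list (1 of 28 rose and 7 fell (1 rose and 9 fell adjusted over the list alone), adjusted p = 7.8e-08). Of the identity list 5 of 30 fell (1 rose and 7 fell adjusted over the list alone), adjusted p = 0.0018, adjusted p = 0.54 with an estimated correlation, CD163, a scavenger receptor gene, by −1.85 ± 0.35. Of the glycolysis and hypoxia list 7 of 24 rose and 2 fell, adjusted p = 0.0067, adjusted p = 0.32 with an estimated correlation, GAPDH by 0.81 ± 0.19 while ACOD1 fell by −4.82. Of the anti-inflammatory list 3 of 25 fell, adjusted p = 0.07, IL18BP by −3.06 ± 0.29 and IDO1 by −1.64 ± 0.30. IL10 gave 0.66 ± 0.41. Of the CREB/CRTC list 3 of 27 rose and 2 fell (6 rose and 3 fell adjusted over the list alone), adjusted p = 0.23, PDE4D by 2.35 ± 0.32 and EGR2 by −3.69 ± 0.55. Of the prostaglandin list 2 of 16 rose and 2 fell (2 rose and 3 fell adjusted over the list alone), adjusted p = 0.028, adjusted p = 0.27 with an estimated correlation, adjusted p = 0.056 with a donor block, PTGS2 and PTGES rising by 0.99 ± 0.26 and 2.58 ± 0.50. Of the NF-kB targets 2 of 26 rose and 2 fell (3 rose and 4 fell adjusted over the list alone), adjusted p = 0.45. Of the heat shock list 3 of 24 rose, adjusted p = 0.78. IL6, IL1B, CXCL8 and CCL2 did not pass (1.22 ± 0.52, 1.02 ± 0.43, 0.89 ± 0.45 and −2.54 ± 0.82). With a donor block adjusted p was 0.036 for IL6, 0.035 for CXCL8 and 0.018 for CCL2. Of the dendritic markers 2 of 9 fell (4 fell adjusted over the list alone), adjusted p = 0.0016, adjusted p = 0.10 with an estimated correlation. The platelet gene PPBP gave 2.56 ± 0.89 (adjusted p = 0.093; 0.0024 with the block; 2422 against 411 CPM). Cells with 10 µM lay in cluster 23 (99.9%). The 897 genes became 391, 557 and 462 without LPS replicate 1, LPS replicate 2 and 10 µM replicate 2. Of 69 named genes that passed, 46, 54, 58 and 51 did so without LPS replicate 1, LPS replicate 2, 10 µM replicate 1 and 10 µM replicate 2 (41 whichever was left out). CXCL10 had adjusted p = 0.202, 0.0604, 0.209 and 0.175 without the same libraries in that order. IL23A had 0.088 and TNF 0.11 without LPS replicate 1, and 0.16 and 0.07 without 10 µM replicate 2. PTGS2 had 0.25 and 0.18 without LPS replicate 2 and 10 µM replicate 2.

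**Figure D3:**
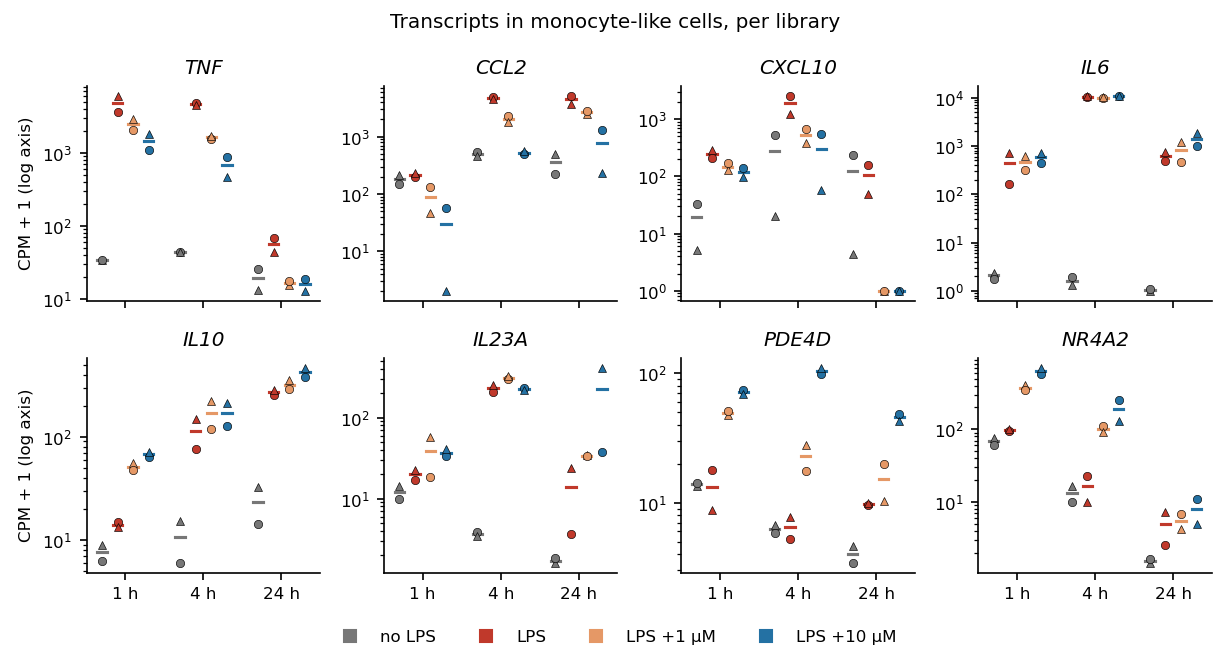
Level of 8 genes in monocyte-like cells, in CPM plus 1 on a log axis, by group and time. Points are the 2 libraries and bars their mean. Among the 3 LPS groups the mean of TNF is lowest and the means of PDE4D and NR4A2 are highest with 10 µM at 1 and 4 h.

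The comparison of 1 µM with 0 µM under LPS asked what the lower dose did. At 1 h, 5 genes rose in monocyte-like cells: CHMP1B (1.27 ± 0.14), DUSP4 (3.14 ± 0.51), PDE4D (1.92 ± 0.31), PRDM1 (1.23 ± 0.20) and EPB41L3 (0.80 ± 0.14). The CREB/CRTC list rose (1 of 27 rose (11 rose adjusted over the list alone), median 0.74, adjusted p = 5.7e-17). NR4A2 gave 1.97 ± 0.38 (adjusted p = 0.11; 0.0074 with a donor block) and IL10 1.94 ± 0.50 (adjusted p = 0.35; 0.0086 with the block). PTGS2 gave 1.17 ± 0.26 (adjusted p = 0.22; 0.046 with the block) and IFNB1 −2.33 ± 0.87 (adjusted p = 0.96; 0.013 with the block). Platelet markers gave 0 of 8 passed, adjusted p = 0.00073, adjusted p = 0.45 with an estimated correlation. T and NK markers had adjusted p = 0.15 (0.046 with the block), and dendritic markers 0.039 (0.057 with the block, 0.33 with an estimated correlation). At 4 h CLGN rose (2.64 ± 0.39) and NLN fell (−2.41 ± 0.35), 2 genes chosen after their values were seen. The CREB/CRTC list gave 0 of 27 passed (9 rose and 1 fell adjusted over the list alone), median 0.61, adjusted p = 1.5e-08, adjusted p = 0.12 with an estimated correlation, SIK pathway components 0 of 18 passed (3 rose and 1 fell adjusted over the list alone), adjusted p = 0.0038, adjusted p = 0.17 with an estimated correlation and interferon-stimulated genes 0 of 40 passed, median −0.31, adjusted p = 0.00031, adjusted p = 0.67 with an estimated correlation. TNF at 4 h gave −1.52 ± 0.34 (adjusted p = 0.087; 0.029 with the block) and NR4A2 2.62 ± 0.45 (adjusted p = 0.053; 0.0042 with the block). At the same time NR4A1 gave 1.37 ± 0.33 (adjusted p = 0.093; 0.03 with the block) and IFNB1 −1.84 ± 1.01 (adjusted p = 0.53; 0.037 with the block). At 24 h 70 genes rose and 190 fell. Of the interferon-stimulated genes 38 of 40 fell (40 fell adjusted over the list alone), median −2.90, adjusted p = 1.5e-119, RSAD2 by −5.04 ± 0.60, IFIT1 by −4.65 ± 0.82 and OAS1 by −3.25 ± 0.32. Of the MHC class II list 7 of 18 fell (10 fell adjusted over the list alone), adjusted p = 3.8e-13, adjusted p = 0.058 with an estimated correlation, CD40 by −1.89 ± 0.35. Of lymphocyte activation genes 5 of 28 fell (1 rose and 8 fell adjusted over the list alone), adjusted p = 2.4e-09. TNF fell, −1.83 ± 0.39 (adjusted p = 0.015; 15.6 against 55.4 CPM). CXCL10 had 0 counts with 1 µM, at least 269-fold (at least 103-fold whichever library was left out) lower than with LPS alone, without passing the test (adjusted p = 0.11; 0.018 with the block). VEGFA rose by 2.38 ± 0.46, OSM by 1.66 ± 0.34 and CD14 by 1.18 ± 0.30. Of the chemokines 1 of 22 rose and 2 fell (3 rose and 6 fell adjusted over the list alone), adjusted p = 0.023, adjusted p = 0.16 with an estimated correlation, adjusted p = 0.23 with a donor block. Of the metallothionein list 1 of 10 fell (2 fell adjusted over the list alone), adjusted p = 0.0018, adjusted p = 0.19 with an estimated correlation. Cells with 1 µM lay in clusters 27 (47.6%), 20 (37%) and 30 (15.1%) at 1 h, 22 (99.1%) at 4 h and 23 (99.8%) at 24 h. A donor block gave 29, 133 and 532 genes at 1, 4 and 24 h against 5, 2 and 260. The 5 genes at 1 h became 1 without 1 µM replicate 2, 2 without 1 µM replicate 1 or LPS replicate 1, and 3 without LPS replicate 2, CHMP1B alone passing whichever was left out. PDE4D had adjusted p = 0.42, 0.20 and 0.26 without LPS replicate 2, 1 µM replicate 1 and 1 µM replicate 2. The 2 genes at 4 h became 6 without 1 µM replicate 1, 1 without LPS replicate 1 and 0 without either other library. The 260 at 24 h became 106, 77 and 81 without 1 µM replicate 1, 1 µM replicate 2 and LPS replicate 1. TNF at 24 h had adjusted p = 0.12, 0.17 and 0.23 without those 3 libraries. Of the 44 named genes, 22, 16, 16 and 32 passed without them and LPS replicate 2.

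Between the doses, 10 µM against 1 µM under LPS, 0 genes passed at 1 h and at 24 h by edgeR (246 and 531 at unadjusted p under 0.05, and 2 and 18 by DESeq2). At 4 h 4 passed, named here after their values were seen. PDE4D (2.27 ± 0.30), SATB1 (1.64 ± 0.24) and CHMP1B (1.36 ± 0.14) were higher and HDAC9 (−1.97 ± 0.31) lower with 10 µM. A donor block gave 43 genes at 4 h and 32 at 24 h. The CREB/CRTC list at 4 h had adjusted p = 0.07 (0.018 with the block). The 4 genes at 4 h became 1 without 1 µM replicate 1, 9 without 10 µM replicate 1 and 2 without 10 µM replicate 2. At 1 h leaving out 10 µM replicate 1 gave 2, and at 24 h leaving out 10 µM replicate 1 or 1 µM replicate 2 gave 8 or 1. All 5 genes that rose with 1 µM at 1 h also rose with 10 µM. At 24 h, 65 genes rose and 183 fell with both doses, against 2.18 and 8.2 for independent lists and at most 1 and 0 in 20 simulations of unchanged groups against the same controls. Genes that LPS raised and 10 µM lowered numbered 10, 305 and 275 at 1, 4 and 24 h, against 0.501, 93.8 and 106 for independent lists and at most 0, 0 and 1 in the simulations. Genes that LPS lowered and 10 µM raised numbered 3, 209 and 61, against 0.551, 121 and 70.7 for independent lists and at most 0, 0 and 1 simulated. Genes changed the same way by LPS and 10 µM numbered 11, 140 and 159 up, against 1.84, 108 and 76.1 for independent lists, and 0, 19 and 94 down, against 0.15, 105 and 97.9. All these comparisons use the libraries with LPS alone. LPS and 10 µM hold them on opposite sides, so part of any excess of opposite changes may come from these shared controls. The same controls work against overlaps changed the same way by LPS and 10 µM. The 2 doses hold them on the same side, so part of the excess common to both doses may come from them. The simulated groups held no changed genes, so hardly any could pass and overlaps near 0 were set in advance. They cannot show how many overlaps shared controls give where many genes change. The values for independent lists leave the shared controls out of account. Over 12073 genes the covariance of the fold changes of LPS and 10 µM was −0.248, −0.737 and −0.274 at 1, 4 and 24 h, against −0.19, −0.361 and −0.183 simulated. The covariance was thus further below 0 than simulated at each time. The correlation was nearer 0 than simulated, −0.383, −0.357 and −0.147 against −0.601, −0.624 and −0.64. The simulation held no changed genes, and changes of any kind add spread that can draw a correlation towards 0. The correlation therefore cannot decide whether the changes oppose beyond the shared controls. The covariance of 1 µM and 10 µM was 0.32, 0.772 and 0.661 against 0.191, 0.357 and 0.183, and their correlation 0.651, 0.642 and 0.791 against 0.542, 0.528 and 0.578. The effect of 10 µM itself was tested between times for the 15 key genes (30 tests). It was higher at 24 h than at 4 h for IL23A (4.33 ± 1.12, adjusted p = 0.034) and lower at 4 h than at 1 h for TNFSF14 (−1.20 ± 0.35, adjusted p = 0.044). For IL10 the difference of 4 h and 1 h was −1.76 ± 0.65 (adjusted p = 0.095; 0.0088 with a donor block). Of the 252 tests of lists in monocyte-like cells 88 passed with the preset correlation of camera, and 27 also with an estimated correlation. With LPS these included the cytokine, chemokine, anti-inflammatory, NF-kB and lymphocyte activation lists at each time, the prostaglandin list at 1 h, the interferon-stimulated genes at 4 h and the metallothioneins at 24 h. With either dose they included the CREB/CRTC list at 1 h and the interferon-stimulated and lymphocyte activation lists at 24 h. The metallothioneins also held at 24 h with 10 µM and between the doses at 24 h (0 of 10 passed (5 fell adjusted over the list alone), median −0.51, adjusted p = 1.8e-09). In T-like, NK-like and B-like cells 29 of 50, 26 of 44 and 10 of 28 calls held.

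The positions of the genes followed most closely are given on GRCh38 (GENCODE 29), each the span of the whole gene. TNF lies on chromosome 6 from 31575567 to 31578336, IL6 on chromosome 7 from 22725884 to 22732002, IL10 on chromosome 1 from 206767602 to 206772494 and IL23A on chromosome 12 from 56334174 to 56340410. CXCL10 lies on chromosome 4 from 76021117 to 76023497, CCL2 on chromosome 17 from 34255218 to 34257203, NR4A2 on chromosome 2 from 156324432 to 156342348 and PDE4D on chromosome 5 from 58969038 to 60522120. IFNB1 lies on chromosome 9 from 21077105 to 21077963 and IFNG on chromosome 12 from 68154768 to 68159747. All are protein-coding, and the 3' libraries counted reads near the end of their transcripts.

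In T-like, NK-like and B-like cells LPS raised interferon-stimulated genes. At 4 h, RSAD2 rose by 8.75 ± 0.29 in T-like cells (729 against 1.69 CPM), 7.54 ± 0.35 in NK-like cells and 7.36 ± 0.41 in B-like cells, and CXCL10 by 9.19 ± 0.85 in B-like cells (630 against 0.947 CPM). Of that list, at 4 h 38 of 39 rose (39 rose adjusted over the list alone), median 3.98, adjusted p = 6.3e-225 in T-like cells, 38 of 39 rose (39 rose adjusted over the list alone), median 4.36, adjusted p = 1.9e-175 in NK-like cells and 38 of 39 rose (39 rose adjusted over the list alone), median 5.15, adjusted p = 5.2e-250 in B-like cells. At 24 h the same classes gave 36 of 39 rose (39 rose adjusted over the list alone), median 3.08, adjusted p = 1.7e-216, 38 of 39 rose, median 2.71, adjusted p = 1.8e-148 and 38 of 39 rose (39 rose adjusted over the list alone), median 2.84, adjusted p = 6.2e-160. Camera with an estimated correlation gave adjusted p = 9.1e-07 in T-like cells at both times. In NK-like cells it gave 3.08e-05 at 4 h and 8.79e-05 at 24 h. IFNG, the interferon gamma gene, rose in NK-like cells at 24 h by 8.74 ± 1.67, a call lost without no LPS replicate 2. Its level was 1780 against 6.81 CPM, with SDs of 2225 and 6.9 over the libraries of each group. CSF2, a growth factor gene, was at least 118-fold (at least 23.9-fold whichever library was left out) higher at 24 h. Of NF-kB targets at 4 h, 16 of 23 rose (18 rose adjusted over the list alone), adjusted p = 1.8e-15 in NK-like cells and 10 of 25 rose (14 rose and 1 fell adjusted over the list alone), adjusted p = 5.5e-05 in T-like cells. Of lymphocyte activation genes 16 of 27 rose (22 rose adjusted over the list alone), adjusted p = 1.7e-19 and 14 of 29 rose and 1 fell, adjusted p = 2.9e-13. IL16 fell in T-like cells at 4 h (−1.94 ± 0.28), KLF2 in NK-like cells at 24 h (−3.77 ± 0.33) and CD79B, a B cell receptor chain gene, in B-like cells at 4 h (−1.89 ± 0.22). The cells compared also lay in different clusters at 4 h: T-like cells in 3, 8 and 11 (40.3, 28.8 and 25.7%) with LPS and in 1, 6 and 25 (35.6, 23.4 and 23.3%) without, NK-like cells in 14 (95.6%) and in 31 (70.7%), and B-like cells in 13 (90.2%) and in 19 (80.4%). At 24 h the largest T-like cluster was 15 (40.1%) with LPS and 1 (48.9%) without, while 80.2 and 87.5% of NK-like cells lay in 12 and 93 and 91.5% of B-like cells in 9. Markers of dendritic cells moved too: at 4 h 1 of 3 rose, median −0.18, adjusted p = 7.9e-05 and mean 1.08 in T-like cells and 1 of 2 rose, median 4.06, adjusted p = 1.7e-06 in NK-like cells, and at 24 h 1 of 3 rose, median 2.43, adjusted p = 5.2e-08 in T-like cells. Of the monocyte identity list 4 of 8 fell (5 fell adjusted over the list alone), median −1.26, adjusted p = 0.0014 in NK-like cells at 24 h, and 2 of 20 fell (3 fell adjusted over the list alone), median −1.36, adjusted p = 0.0033, adjusted p = 0.24 with an estimated correlation in T-like cells. At 1 h T-like, NK-like and B-like cells gave 2, 0 and 1 genes by edgeR (153, 236 and 261 at unadjusted p under 0.05, and 5, 3 and 1 by DESeq2; 2, 5 and 3 with a donor block). These genes, named after their values were seen, were IL1B (3.87 ± 0.43) and CXCL3 (6.48 ± 0.84) in T-like cells and IL1B (3.51 ± 0.52) in B-like cells, each far higher in monocyte-like cells. Leaving out no LPS replicate 1 or 2 gave 0 in T-like cells and LPS replicate 2 gave 1. The single B-like gene became 2 without LPS replicate 1 and 0 without any other library. As lists, cytokines, chemokines and NF-kB targets rose at 1 h in T-like and NK-like cells. Camera with an estimated correlation gave adjusted p = 0.00107, 0.00637 and 0.0396 in T-like cells. In NK-like cells, where no member passed, it gave 0.00482, 0.0025 and 0.00707. The monocyte identity list fell in T-like cells at 1 h (adjusted p = 0.000131, 0.119 with an estimated correlation). Free RNA was not tested as a source at 1 h. At 4 h 792 genes rose and 426 fell in T-like, 805 and 365 in NK-like and 576 and 148 in B-like cells. At 24 h the numbers were 481 and 278, 378 and 193, and 311 and 263. A donor block gave 2550 and 1790 genes at 4 h in T-like and NK-like cells, and 2082, 1071 and 1077 at 24 h in T-like, NK-like and B-like cells. At 4 h, leaving out no LPS replicate 2 or LPS replicate 2 gave totals of 774 or 779 genes in T-like cells, against 1218, and 677 or 615 in NK-like cells, against 1170. Without LPS replicate 2 the B-like total was 475, against 724. At 24 h, leaving out no LPS replicate 1, no LPS replicate 2, LPS replicate 1 or LPS replicate 2 gave totals of 444, 289, 317 or 454 in T-like cells, against 759, and 366, 257, 275 or 371 in B-like cells, against 574. The first 3 gave 371, 195 or 288 in NK-like cells, against 571. Such totals can hold genes that had not passed before. With stricter cell filters the totals were 724, 648 and 258 at 4 h in T-like, NK-like and B-like cells, and 426 and 236 at 24 h in T-like and B-like cells. At 4 h a fit of that time alone gave 745 in T-like cells. In NK-like cells DESeq2 gave 681 and 311 at 4 and 24 h, and thinning 666 and 338.

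With 10 µM under LPS, interferon-stimulated genes fell in the lymphoid classes too. At 24 h, 32 of 39 fell (38 fell adjusted over the list alone), median −2.18, adjusted p = 1.1e-207 in T-like cells, 31 of 39 fell (37 fell adjusted over the list alone), median −1.55, adjusted p = 4.9e-83 in NK-like cells and 34 of 39 fell (38 fell adjusted over the list alone), median −1.55, adjusted p = 2.1e-69 in B-like cells, against 40 of 40 in monocyte-like cells. Camera with an estimated correlation gave adjusted p = 9.45e-07 in T-like and 0.000322 in NK-like cells. RSAD2 fell in T-like cells by −3.83 ± 0.23 (11.5 against 165 CPM). At 4 h, 12 of 39 fell (28 fell adjusted over the list alone), median −0.83, adjusted p = 1.7e-46 in T-like, 3 of 39 fell (12 fell adjusted over the list alone), median −0.56, adjusted p = 1.1e-20 in NK-like and 11 of 39 fell (31 fell adjusted over the list alone), median −0.76, adjusted p = 1.6e-36 in B-like cells. Camera with an estimated correlation gave adjusted p = 0.00109 in T-like and 0.0238 in NK-like cells at 4 h. CXCL10 changed by −4.74 ± 0.60, −5.36 ± 0.87 and −3.89 ± 0.55 in T-like, NK-like and B-like cells. The NK-like call was lost without LPS replicate 1 (adjusted p = 0.064) or 10 µM replicate 2 (0.14). In NK-like cells IFNG at 24 h changed by −4.68 ± 1.18 (edgeR adjusted p = 0.046), a call lost without 10 µM replicate 2 or LPS replicate 1. Its level was 82.2 against 1780 CPM, with SDs of 112.7 and 2225 over the libraries of each group. CCL3 at 24 h changed by −3.71 ± 0.34. BATF, an activation factor gene, fell at 4 h by −2.19 ± 0.20. Of lymphocyte activation genes in NK-like cells at 4 h 6 of 27 fell (11 fell adjusted over the list alone), adjusted p = 4.3e-14. At 24 h 1 of 27 rose and 6 fell (1 rose and 14 fell adjusted over the list alone), adjusted p = 1.8e-14. Camera with an estimated correlation gave adjusted p = 0.024 and 0.0244 at these times. CREB/CRTC targets in T-like cells gave 0 of 26 passed (2 rose adjusted over the list alone), median 0.51, adjusted p = 2e-14 at 1 h and 6 of 26 rose (9 rose and 1 fell adjusted over the list alone), adjusted p = 4.2e-05, adjusted p = 0.064 with an estimated correlation at 24 h, CREM by 1.63 ± 0.22 (200 against 64.6 CPM). In B-like cells at 24 h they gave 8 of 24 rose (11 rose and 1 fell adjusted over the list alone), adjusted p = 5.3e-08, adjusted p = 0.09 with an estimated correlation. RGS2, a regulator of G protein signalling, rose in B-like cells at 24 h by 3.85 ± 0.41 (142 against 9.64 CPM) and in NK-like cells by 2.29 ± 0.35. Of the MHC class II list 1 of 17 rose and 8 fell (2 rose and 12 fell adjusted over the list alone), adjusted p = 1.8e-09 in B-like cells at 24 h. At 24 h 40.1% of T-like cells lay in cluster 15 with LPS alone and 0.515% with 10 µM, against 3.61 and 45.5% in cluster 1. NK-like cells lay in 12 (80.2% with LPS alone, 81.5% with 10 µM) and B-like cells in 9 (93 and 88.9%). At 4 h dendritic markers gave 0 of 2 passed (1 fell adjusted over the list alone), median −0.56, adjusted p = 0.0014 in NK-like cells and 1 of 3 fell, adjusted p = 0.026, adjusted p = 0.098 with an estimated correlation in T-like cells, and B markers 2 of 9 fell (3 fell adjusted over the list alone), adjusted p = 0.00046, adjusted p = 0.48 with an estimated correlation in B-like cells. Marker lists moved as well at 24 h: in NK-like cells T and NK markers gave 2 of 12 fell (4 fell adjusted over the list alone), adjusted p = 9.1e-05, adjusted p = 0.15 with an estimated correlation and B markers 0 of 3 passed (2 fell adjusted over the list alone), median −2.20, adjusted p = 0.0095, adjusted p = 0.051 with an estimated correlation, in T-like cells dendritic markers 1 of 3 fell, median 0.49, adjusted p = 1.4e-05 and mean −0.90, and in B-like cells B markers 3 of 9 fell (4 fell adjusted over the list alone), adjusted p = 0.00016, adjusted p = 0.43 with an estimated correlation. At 1 h T-like, NK-like and B-like cells gave 2, 0 and 0 genes by edgeR (408, 312 and 541 at unadjusted p under 0.05, and 22, 0 and 0 by DESeq2; 72, 3 and 15 with a donor block). The T-like pair, named after its values were seen, was LYPD3 (1.02 ± 0.15) and GIMAP6 (−0.87 ± 0.12), and leaving out any 1 of the 4 libraries gave 0. In B-like cells LPS replicate 1 and 10 µM replicate 1 gave 1 and 2 when left out. At 4 h 45 rose and 119 fell in T-like, 19 and 59 in NK-like and 84 and 144 in B-like cells. At 24 h the numbers were 115 and 211, 44 and 126, and 327 and 336. A donor block gave 897, 419 and 568 genes at 4 h and 1132, 501 and 1224 at 24 h. Leaving out LPS replicate 1, LPS replicate 2, 10 µM replicate 1 or 10 µM replicate 2 gave, at 4 h, totals of 29, 80, 60 or 34 in T-like cells (against 164), 26, 23, 25 or 16 in NK-like cells (against 78) and 71, 81, 62 or 64 in B-like cells (against 228). At 24 h the same omissions gave 130, 164, 170 or 119 in T-like cells (against 326) and 264, 409, 295 or 316 in B-like cells (against 663). Without 10 µM replicate 1 or 2 the NK-like total was 78 or 66 (against 170). With stricter cell filters the totals were 53, 42 and 22 at 4 h in T-like, NK-like and B-like cells, and 206 and 271 at 24 h in T-like and B-like cells. At 4 h a fit of that time alone and DESeq2 gave 19 and 253 in T-like cells, and DESeq2 and thinning 49 and 39 in NK-like cells. Testing without a filter on low counts gave 460, 201 and 491 at 4 h, and 594 and 324 at 24 h in T-like and NK-like cells. Differences between the classes were not tested.

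**Figure D4:**
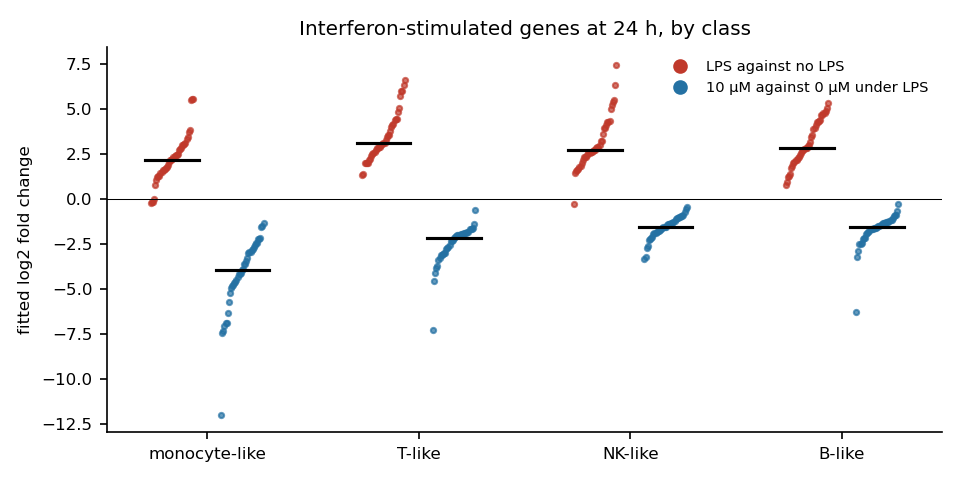
Fitted log2 fold change of each interferon-stimulated gene with 10 µM against 0 µM under LPS at 24 h, by cell class. Points are genes and black lines the medians (−3.91 in monocyte-like cells and −2.18, −1.55 and −1.55 in T-like, NK-like and B-like cells). The lowest monocyte-like point is CXCL10, which had 0 counts with 10 µM.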

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

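Of the tests in this part, those on the unnamed share of cells were chosen after the result was seen. In monocyte-like cells the effect of 10 µM was tested between times by the difference itself, with edgeR p adjusted over the key gene tests. It differed for TNFSF14 by −1.204 on the log2 scale between 4 h and 1 h (adjusted p = 0.0437). For IL23A it differed by 4.33 between 24 h and 4 h (adjusted p = 0.0344). Adjusted over all genes, IL23A still passed (0.0445) and TNFSF14 did not (0.12). Over all 12073 genes, 85 differed between 4 h and 1 h and 337 between 24 h and 4 h.

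The fall of interferon-stimulated genes with 10 µM at 24 h came in 137 cases over the 4 classes. Depth is argued against, since 94.2% of the 137 also fell on sums thinned to 1 total per class. So is a shift of scale from a few genes taking most of the counts, since the median unscaled change of all genes reached at most 4.04% of the list's median in any class. Free RNA from monocyte-like cells as the source in T-like, NK-like and B-like cells is argued against as well, since the list's level relative to monocyte-like cells was at least 314 times that of monocyte marker genes. A biological effect of the compound on interferon signalling remains a hypothesis, found and tested on the same data.

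The monocyte-like share was lower with LPS in 6 of 6 pairs, by −9.21 points (SE 0.995), and higher with 10 µM in 6 of 6. Monocyte-like cells hidden in unnamed clusters are argued against for LPS, where the unnamed share moved by −0.289 points (SE 0.40), and for 10 µM, where it rose by 0.358 points (SE 0.31). Barcodes left out by the gene and mitochondrial filters are argued against too: their share moved by 0.922 points (SE 0.61) with LPS and 1.14 points (SE 0.69) with 10 µM, the latter the same way as the monocyte-like share. Loss of cells on the dish could also change the share, and was not tested, since the files hold only recovered cells. The share tests missed the threshold, but with 6 pairs p cannot go below 0.03125, so this says little against the change, whose cause stays open.

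In T-like, NK-like or B-like cells 10 cytokine and chemokine genes rose with LPS at 24 h. Free RNA from monocyte-like cells as the source of all of them is argued against. With LPS alone 4 were counted as at least 5-fold apart between the classes in both libraries. For CCL3 this rested on measured levels in all classes. CSF2 had 1 count in B-like cells, so 0 in 1 library, and CXCL10 had 2 counts in NK-like cells. CXCL9 had 0 counts in NK-like cells. For the 5 genes with levels within 3-fold in the 3 classes (CXCL1, CXCL3, CXCL5, CXCL8 and IL1B), at about 0.1% of the monocyte-like level, free RNA cannot be told apart from own expression. Their share of the monocyte-like level over that of marker genes was 0.629 in T-like, 0.618 in B-like and 0.159 in NK-like cells, where a ratio near 1 would fit free RNA; NK cells make several of the marker genes themselves, which lowers their ratio.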

How the results depend on the processing

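Of the alternatives in this part, only leaving out the CD16 monocyte cluster was chosen after the data were seen. No result that passed reversed. Over RLE size factors, no filter on low counts, DESeq2 and a donor block, 2149 of 2176 values of the 544 named genes that passed still passed and 27 no longer did; of 1812 values of the 453 that had not passed, 279 then passed. Leaving out 1 library ended 469 of 2174 such calls and added 17 of 1812. The donor block ended none of the 544 calls, added 76 of the 453 others, and over the list tests added 24 calls and ended 7; it also added the IL10 difference of the 10 µM effect between 4 h and 1 h (adjusted p = 0.0088). RLE size factors moved 0 of 30 counts of genes by more than 1.5 times and the median of all genes by at most 0.0922, for LPS at 4 h in monocyte-like cells, where the share of calls that rose went from 47.2% to 53.4%. For 10 µM at 24 h it went from 41.9% to 33.9%. Of 36 other values of the shares 28 kept their side of the threshold; with 1 pair left out no share test can pass, so those tests are not read. The stricter filters changed the sign of the NK-like share with 10 µM (−2.54 points) and 1 µM (−1.11), and gave 3.67 for the NK-like share with LPS, −0.648 and −0.499 for the T-like share with 10 and 1 µM and 2.8 for the monocyte-like share with 1 µM. In the simulated comparisons 2-fold changes were recovered least often in monocyte-like and NK-like cells (54% and 57%). Fewer genes tested, cells or UMIs are built into the stricter filters, thinning and left-out libraries; otherwise the cause of a move was not tested.

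Counts of genes that passed and moved by more than 1.5 times follow, with LPS for LPS against no LPS, and 10 µM or 1 µM for that dose against 0 µM under LPS. A donor block gave in monocyte-like cells 167 for 10 µM at 1 h, 29, 133 and 532 for 1 µM at 1, 4 and 24 h, 43 and 32 for 10 against 1 µM at 4 and 24 h. With the block, T-like cells gave 72, 897 and 1132 for 10 µM at 1, 4 and 24 h, 2550 and 2082 for LPS at 4 and 24 h. With the block, NK-like cells gave 5, 1790 and 1071 for LPS at 1, 4 and 24 h, 3, 419 and 501 for 10 µM at 1, 4 and 24 h. With the block, B-like cells gave 3 and 1077 for LPS at 1 and 24 h, 15, 568 and 1224 for 10 µM at 1, 4 and 24 h. Testing without a filter on low counts gave in monocyte-like cells 296 for 10 µM at 1 h, 110, 308 and 672 for 1 µM at 1, 4 and 24 h, 18, 184 and 169 for 10 against 1 µM at 1, 4 and 24 h. Without the filter, T-like cells gave 13 for LPS at 1 h, 56, 460 and 594 for 10 µM at 1, 4 and 24 h. Without the filter, NK-like cells gave 11 for LPS at 1 h, 4, 201 and 324 for 10 µM at 1, 4 and 24 h. Without the filter, B-like cells gave 11 for LPS at 1 h, 46 and 491 for 10 µM at 1 and 4 h. DESeq2 gave in monocyte-like cells 106 for 10 µM at 1 h, 15 and 66 for 1 µM at 1 and 4 h, 2, 32 and 18 for 10 against 1 µM at 1, 4 and 24 h. By DESeq2, T-like cells gave 5 for LPS at 1 h, 22 and 253 for 10 µM at 1 and 4 h. By DESeq2, NK-like cells gave 3, 681 and 311 for LPS at 1, 4 and 24 h, 49 for 10 µM at 4 h. The stricter cell filters gave in monocyte-like cells 3 and 7 for 1 µM at 1 and 4 h. With stricter filters, T-like cells gave 0, 53 and 206 for 10 µM at 1, 4 and 24 h, 724 and 426 for LPS at 4 and 24 h. With stricter filters, NK-like cells gave 648 for LPS at 4 h, 42 for 10 µM at 4 h. With stricter filters, B-like cells gave 0, 258 and 236 for LPS at 1, 4 and 24 h, 22 and 271 for 10 µM at 4 and 24 h. A fit of the 1 time point gave in monocyte-like cells 3, 5 and 57 for 1 µM at 1, 4 and 24 h, 491 for 10 µM at 24 h. With that fit, T-like cells gave 0 and 745 for LPS at 1 and 4 h, 0 and 19 for 10 µM at 1 and 4 h. Thinning to the smallest total gave in monocyte-like cells 3 and 21 for 1 µM at 1 and 4 h. After thinning, T-like cells gave 1 for LPS at 1 h. After thinning, NK-like cells gave 666 and 338 for LPS at 4 and 24 h, 39 for 10 µM at 4 h. After thinning, B-like cells gave 0 for LPS at 1 h. Overlaps with the block were 20 for LPS up and 10 µM down at 1 h, 11 and 108 for LPS down and 10 µM up at 1 and 24 h, 25, 86 and 153 for both doses up at 1, 4 and 24 h, 4, 43 and 338 for both doses down at 1, 4 and 24 h. Overlaps without a filter were 57 for LPS up and 10 µM down at 1 h, 14 and 110 for LPS down and 10 µM up at 1 and 24 h, 80, 179 and 210 for both doses up at 1, 4 and 24 h, 21, 97 and 390 for both doses down at 1, 4 and 24 h. Overlaps by DESeq2 were 15 and 34 for both doses up at 1 and 4 h, 132 and 39 for LPS down and 10 µM up at 4 and 24 h, 31 for both doses down at 4 h. Leaving out 1 library gave in monocyte-like cells 270 to 429 for LPS at 1 h; 13 to 75, 420 to 750 and 391 to 693 for 10 µM at 1, 4 and 24 h; 1 to 3, 0 to 6 and 77 to 176 for 1 µM at 1, 4 and 24 h; 0 to 2, 1 to 9 and 0 to 8 for 10 against 1 µM at 1, 4 and 24 h. Leaving out 1 library gave in T-like cells 0 to 2, 774 to 832 and 289 to 454 for LPS at 1, 4 and 24 h; 0 to 0, 29 to 80 and 119 to 170 for 10 µM at 1, 4 and 24 h. Leaving out 1 library gave in NK-like cells 615 to 929 and 195 to 622 for LPS at 4 and 24 h; 16 to 26 and 66 to 183 for 10 µM at 4 and 24 h. Leaving out 1 library gave in B-like cells 0 to 2, 475 to 507 and 257 to 371 for LPS at 1, 4 and 24 h; 0 to 2, 62 to 81 and 264 to 409 for 10 µM at 1, 4 and 24 h. Keeping predicted doublets gave 11 genes for 1 µM at 4 h in monocyte-like cells, leaving out the CD16 monocyte cluster 1 for 1 µM at 1 h, and leaving out genes far higher in monocyte-like cells 0 for LPS at 1 h in T-like and in B-like cells.

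With predicted doublets kept, 8 of the 12 share tests had adjusted p = 0.0469 by the exact permutation test. With LPS the monocyte-like share then differed by −9.34 points, the T-like by 6.9, the NK-like by 0.794 and the B-like by 2.01. With 10 µM the monocyte-like share differed by 3.18 points. With 1 µM the monocyte-like share differed by 1.63 points, the T-like by −1.42 and the B-like by −1.03. Shares of a library add up to the whole, so these 8 differences are not independent. An estimated correlation lowered the lists called from 88, 50, 44 and 28 to 27, 29, 26 and 10 in monocyte-like, T-like, NK-like and B-like cells. List members that passed went from 942 to 1552 in monocyte-like, 305 to 549 in T-like and 306 to 482 in B-like cells without the filter, and to 563 in T-like and from 329 to 517 in NK-like cells with the donor block. Key gene differences between times went from 2 to 20 without the filter and to 4 by DESeq2.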

Other observations

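The tests on IFNB1 and IFNG in this part were chosen after the result was seen. Beyond interferon genes, 10 µM changed other genes in the lymphoid classes. In T-like cells at 24 h FTH1, the ferritin heavy chain gene, rose by 1.91 ± 0.32 (8475 against 2249 CPM) and DDIT4, a stress-induced inhibitor of mTOR signalling, by 1.85 ± 0.34. With each of the 4 libraries left out in turn these calls held 2 and 1 times. At 4 h the transcription factor gene ZNF331 rose in T-like cells (1.70 ± 0.26, held 2 of 4 times) and PDE4A, a cAMP phosphodiesterase gene, in B-like cells (2.24 ± 0.30, 4 of 4). In B-like cells CCL22, a chemokine gene, fell with LPS at 24 h (−2.35 ± 0.55) and rose with 10 µM (2.87 ± 0.55), each held 2 of 4 times, while CCL4 fell with 10 µM (−3.38 ± 0.80, 1 of 4).

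In NK-like cells LPS lowered at 24 h FGFBP2, a gene of cytotoxic NK cells (−3.22 ± 0.43, held 4 of 4 times). With 10 µM RAMP1, a co-receptor gene for calcitonin gene-related peptide, rose at 24 h (1.96 ± 0.35, 3 of 4), while CCL1 fell at 24 h (−5.17 ± 0.53, 3.33 against 139 CPM, 4 of 4) and IL2RA, an interleukin 2 receptor chain gene, at 4 h (−1.73 ± 0.32, 1 of 4). In monocyte-like cells LPS at 24 h raised the platelet-type gene GNG11 (7.63 ± 0.61, 4 of 4) beside PPBP.

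The lower interferon-stimulated genes at 24 h may follow less interferon made earlier in the culture. IFNB1 in monocyte-like cells at 4 h changed by −3.78 with 10 µM (adjusted p = 0.085, and 0.0003 with a donor block). With the block IFNB1 also passed as lower with 10 µM at the earliest time. With the lower dose it did so at the earliest time and at 4 h. Without the block it passed in none of these comparisons. IFNG in NK-like cells at 4 h changed by −4.06 with 10 µM and did not pass (adjusted p = 0.12). No value with the block is given for IFNG. The IFNB1 call thus depends on pairing the donors in the fit, and these values leave the hypothesis open. Less transcript at 24 h of the receptor chains IFNAR1 and IFNAR2 and the kinases JAK1 and TYK2 is argued against as a source common to all classes. Their median change at 24 h over the 4 classes was −0.00838, and 0 of 16 tests fell. Earlier times were not part of this test. The largest change was that of IFNAR2 in monocyte-like cells (−0.512 ± 0.168, edgeR adjusted p = 0.0747). Less IFNAR2 in that class stays open. Protein and secreted interferon were not analysed here.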
